A study of Brachypodium distachyon with 4 samples.

How the data were processed

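Messenger RNA was sequenced from leaves of Brachypodium distachyon, a small temperate grass used as a model for wheat and barley. The wild type was the inbred line Bd21-3 and the mutant was jmj1-1, with 2 libraries of each. Per the labels, plants were sampled on day 17 at leaf stage 4, 10 h after lights on in days of 20 h light and 4 h dark. The libraries came from total RNA and a stranded mRNA kit, per the labels' protocols.

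The deposited table holds whole-number read counts per gene with 1 column per library, per the file header and its values. The deposited counts differ in their column totals, as counts without normalisation do. The submitters' processing notes name cutadapt, HISAT2, SAMtools and featureCounts, without versions. The genome build, the annotation release, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. Reads of overlapping genes, antisense pairs and close relatives such as the FT-like or VRN1-like genes could therefore have been split or shared, and their values carry that uncertainty.

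Each column name equals the title of 1 sample, and groups and replicate numbers were read from the titles. The labels do not say whether the 2 libraries of a genotype came from separate plants, so p-values measure only the spread between these samples, which may be technical. The table lists 35125 identifiers, of which 34310 are BRADI loci and 815 are ENSRNA non-coding loci, and 6707 had no read in any library. Depth was 16520046 and 16130508 counted reads in the Bd21-3 libraries and 16089629 and 13825916 in the jmj1-1 libraries. The replicates were not copies of each other. Over genes with enough reads, the chi-square of counts per degree of freedom was 2.41 between the Bd21-3 libraries and 1.85 between the jmj1-1 libraries, against 9.02 for replicate 1 of each genotype.

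Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, which left 21456 genes, and libraries were scaled by TMM. The comparison of jmj1-1 with Bd21-3 used edgeR's quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05, without a fold minimum. Adjusted p-values for genes come from this test unless another test or setting is named beside them. CPM values, the usual per-library scaling of counts, used the TMM-scaled library sizes and were computed here from the deposited counts. Standard errors of log2 fold changes are approximate, being the absolute log2 fold change divided by the square root of the F statistic. For genes with few reads, the ratio of the summed reads of the genotypes is given with an exact 95% Clopper-Pearson interval, and a count of 0 was replaced by a floor of 3 reads over both libraries of a genotype. These intervals and floors cover counting error only.

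Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry. No table used here joins BRADI identifiers to descriptions: the RefSeq gene table of assembly Brachypodium_distachyon_v3.0 matched none of them, so lists planned from descriptions, among them the JmjC demethylases and markers of other cell types, were not analysed here. The 2 lists fixed by locus number before the data were examined, flowering time and circadian clock, were used. The files used here do not pair identifiers with gene names. The names of these loci are published assignments cited from general knowledge, and they could not be checked against a table here. Another 4 lists of such loci were added after the identifiers were seen and before their values were, covering secondary-wall and lignin genes, stomatal lineage genes, auxin transport genes and reference genes. These added lists are exploratory.

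Named genes followed a rule fixed before the data were examined. It took the 12 called genes with the largest fold change in each direction at a mean of 5 CPM or more in the higher genotype, the main flowering regulators whatever their p, and list members. Without descriptions, identifiers were limited to 2 in each direction. BRADI_2g60970v3 and BRADI_2g61050v3 were chosen after their values were seen. Counts were simulated for the same comparison with real means and library sizes, and with dispersions smoothed over expression level. Changed genes were planted only above a mean of 1 CPM. The test recovered 40% of genes planted at 1.25-fold, 74% at 1.5-fold, 84% at 2-fold and 100% at 4-fold among 21197 genes. Of its 159 calls, 2.52% were unchanged genes. Recovery below that mean, and dispersions that vary between genes of like expression, were not covered.

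Alternatives covered other scalings (RLE, upper quartile, library totals and, chosen after seeing the data, TMM factors squared, the mirror image of library totals around TMM), other filters, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, edgeR's older quasi-likelihood method (chosen after seeing the data), the replicate number as a block, a stricter threshold, a test against a fold of 1.5 and leaving out each library. The locus of JMJ1 is not given in the sources used here, so the mutated gene was not checked in the libraries and every direction rests on the labels. Analyses that need gene sequence, length or GC content were not done.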

Results

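Leaf transcripts were counted in 2 libraries of the Brachypodium wild type Bd21-3 and 2 libraries of the mutant jmj1-1, collected at the same hour of a long day. JMJ names are given to JmjC-domain proteins, a family of histone demethylases. The comparison asks which leaf genes differ in the mutant. The locus of JMJ1 is not given in the sources used here, so its own transcript did not check the labels. Gene names are published locus assignments that the files do not state. Total counts ranged from 13825916 to 16520046 reads per library, and between 25946 and 26429 genes had at least 1 read. The libraries separated by genotype. The first principal component of log CPM held 68.0% of the variance and split Bd21-3 from jmj1-1. Across genes, Pearson's r was 0.991 between the Bd21-3 replicates, 0.992 between the jmj1-1 replicates and at most 0.979 between genotypes. Genes are not independent replicates in these correlations. The coefficient of variation within genotypes, which edgeR terms biological, was 3.74%. It may be technical, since the labels do not say that the libraries came from separate plants.

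The flowering genes VRN1, FT1, FUL2 and FT2 were close to silent in jmj1-1 leaves. VRN1 (BRADI_1g08340v3), a MADS-box factor that promotes flowering in temperate grasses, was at 12.4 ± 0.33 CPM in Bd21-3 and 0.066 ± 0.0067 CPM in jmj1-1 (SD, n = 2 each). FT1 (BRADI_1g48830v3), the grass florigen gene, was at 9.77 ± 0.42 CPM in Bd21-3 and 0.132 ± 0.013 CPM in jmj1-1. FUL2 (BRADI_1g59250v3), a FRUITFULL-like relative of VRN1, was at 5.21 ± 0.76 CPM and 0.0967 ± 0.037 CPM. FT2 (BRADI_2g07070v3), another FT-like gene, was at 1.12 ± 0.018 CPM and 0.0307 ± 0.043 CPM.

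Few reads in the mutant limited the precision of these falls. VRN1 had 396 reads over both Bd21-3 libraries and 2 over both jmj1-1 libraries, a ratio of 188 after scaling (95% interval 51.8 to 1560). FT1 had 313 and 4 reads, a ratio of 74.4 (28.8 to 275). FUL2 had 167 and 3 reads, a ratio of 52.9 (17.8 to 259), and FT2 had 36 reads and 1 read, a ratio of 34.2 (5.76 to 1389). In edgeR's quasi-likelihood test the adjusted p-values were 4.66e-24 for VRN1, 8.36e-21 for FT1, 1.09e-14 for FUL2 and 1.80e-05 for FT2. Each of these genes was lower in both jmj1-1 libraries than in either Bd21-3 library. The log2 change of FT2 was -4.79, and it was -4.03 without jmj1-1 replicate 2. Without jmj1-1 replicate 1 no read of FT2 was left in the mutant, and the fitted value of -7.12 is no bound.

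**Figure D1:**
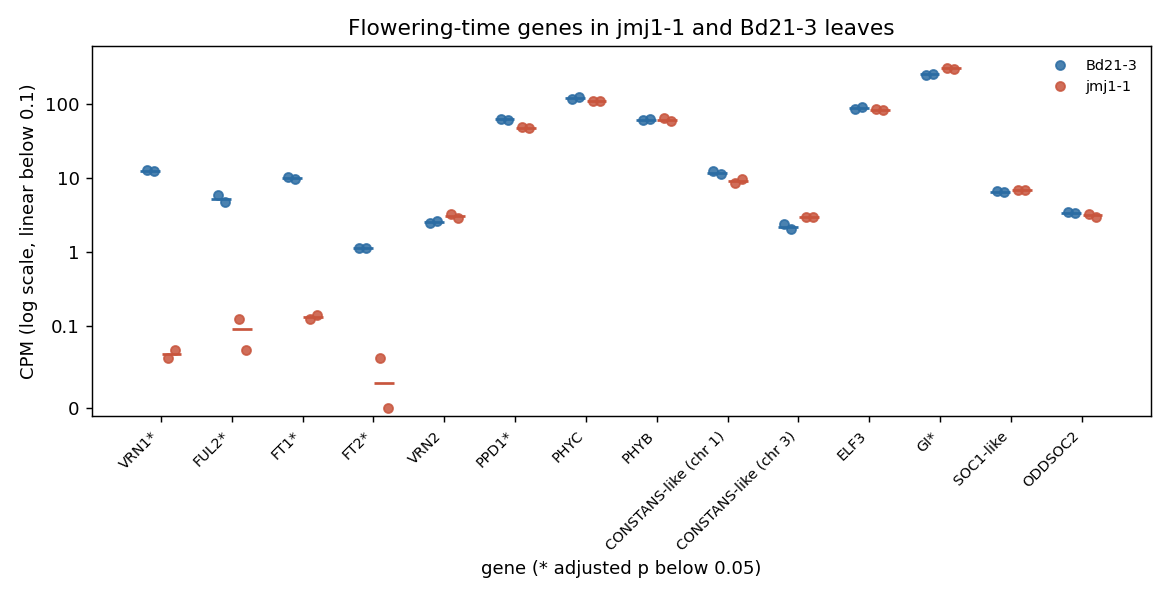
CPM of the 14 tested flowering-time genes in each library, on an axis that is logarithmic above 0.1 CPM and linear below it; points are libraries and horizontal bars are the means of 2 libraries. VRN1, FUL2, FT1 and FT2 lie at or below 0.142 CPM in jmj1-1, while the other genes differ by less than 1.34-fold.

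Light and photoperiod regulators differed far less between the genotypes. PPD1 (BRADI_1g16490v3), a pseudo-response regulator of photoperiod response, fell from 61.7 ± 1.1 to 47.5 ± 1.6 CPM, a log2 change of -0.38 (SE 0.064, adjusted p = 8.85e-06). GI (BRADI_2g05226v3), the GIGANTEA gene of the clock output, rose from 247.0 ± 8.1 to 298.5 ± 2.3 CPM, a log2 change of 0.27 (SE 0.042, adjusted p = 9.72e-07). The light receptor gene PHYC (BRADI_1g08400v3) was at 120.0 ± 4.7 and 109.7 ± 0.16 CPM and did not pass the test over all genes (adjusted p = 0.083). Without Bd21-3 replicate 1 it passed, at a log2 change of -0.17 and adjusted p = 0.026, and with TMM factors squared, at -0.18 and adjusted p = 0.0078, within a range of 0.0078 to 0.44 over the alternatives. VRN2 (BRADI_3g10010v3), a repressor of flowering before vernalization, was at 2.50 ± 0.13 and 3.01 ± 0.25 CPM (adjusted p = 0.59), and its 39 to 52 reads per library limited what could be detected. ELF3 (BRADI_2g14290v3), a component of the evening complex, was at 86.8 ± 2.4 and 82.5 ± 1.2 CPM (adjusted p = 0.47). ODDSOC2, SOC1-like and the CONSTANS-like genes on chromosomes 1 and 3 did not pass the test either, with log2 changes of -0.10, 0.07, -0.36 and 0.42. With TMM factors squared, the CONSTANS-like gene of chromosome 1 passed (adjusted p = 0.030, within a range of 0.030 to 0.53).

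Of the 16 loci on the flowering-time list, 15 were in the file and 14 had enough reads to test. Of these, 5 fell, 1 rose and 8 did not pass the test over all genes. Adjusted over the list alone, 7 fell and 1 rose, with PHYC and the CONSTANS-like gene of chromosome 1 added. The list ranked lower than other genes (camera, median log2 change -0.11, mean -1.71, adjusted p = 2.30e-09). With an estimated correlation it did so at adjusted p = 0.046, close to the threshold. Adjustment was over the 2 lists fixed before the data were examined, and the added lists were adjusted separately. The mean lies far below the median because of VRN1, FT1, FUL2 and FT2, while every other tested member differed by less than 1.34-fold. Fry, which tests the members against no change and not against other genes, gave adjusted p = 6.13e-04.

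The circadian clock genes went both ways. Of 9 tested members, 2 were lower, 2 were higher and 5 did not pass the test, both over all genes and adjusted over the list alone. LHY (BRADI_3g16515v3), the morning MYB gene of the clock, fell from 573.3 ± 2.6 to 440.3 ± 4.2 CPM, a log2 change of -0.38 (SE 0.038, adjusted p = 4.18e-12). PRR95 (BRADI_4g36077v3), a pseudo-response regulator, rose from 47.2 ± 3.2 to 60.7 ± 4.8 CPM, a log2 change of 0.37 (SE 0.067, adjusted p = 3.15e-05). The other called members were PPD1 and GI. For LHY, PRR95, PPD1 and GI, both jmj1-1 libraries lay on the same side of both Bd21-3 libraries. TOC1 (log2 change -0.09) and LUX (-0.15) did not pass the test. As a list, clock genes did not rank apart from other genes (camera adjusted p = 0.25, median log2 change -0.07, and p = 0.35 with an estimated correlation). Every plant was collected at a single hour, so the data hold no rhythm.

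Secondary-wall and lignin genes, a list added after the identifiers were known, were higher in jmj1-1 by small factors. All 8 members rose, over all genes and adjusted over the list alone. The cellulose synthase genes CESA4 and CESA8 of the secondary wall had log2 changes of 0.27 (SE 0.047) and 0.28 (SE 0.043). PAL2, which encodes the entry enzyme of phenylpropanoid synthesis, had 0.25 (SE 0.041). COMT6, a lignin methyltransferase gene, had 0.21 (SE 0.038), and CAD1, a cinnamyl alcohol dehydrogenase gene, had 0.49 (SE 0.11). The smallest changes were at CESA7, 4CL1 and PAL1, with 0.15, 0.18 and 0.18. Camera called the list at adjusted p = 2.83e-06. The call was lost with an estimated correlation (adjusted p = 0.51), and fry did not call the list either (adjusted p = 0.051). Without jmj1-1 replicate 1, CESA7, PAL1 and 4CL1 lost their calls (adjusted p = 0.37, 0.18 and 0.16, the highest of their alternatives, against lowest values of 3.33e-04, 1.10e-07 and 7.27e-04). 4CL1 was also lost without jmj1-1 replicate 2 and without Bd21-3 replicate 1 (adjusted p = 0.074 and 0.088), and CAD1, CESA7 and 4CL1 in DESeq2 (0.073, 0.11 and 0.16). Without the expression filter, CESA7, PAL1 and 4CL1 were lost (0.088, 0.058 and 0.065), and with TMM factors squared CESA7 and 4CL1 (0.15 and 0.11).

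Changes of this size also occurred at 4 of 6 genes that are widely used as expression references. UBI10 and UBI4, polyubiquitin genes, were higher in jmj1-1 by 0.26 and 0.15 on the log2 scale. GAPDH was higher by 0.11, and SAMDC, an S-adenosylmethionine decarboxylase gene, fell by 0.20. ACT3 (-0.04) and UBC18 (-0.10) did not pass the test. ACT3 turned to 0.0126 when libraries were scaled by their totals alone. As a list they did not rank apart (camera adjusted p = 0.45). GAPDH lost its call without Bd21-3 replicate 1 or either jmj1-1 replicate (adjusted p = 0.26, 0.34 and 0.14), and UBI4 without Bd21-3 replicate 1 or jmj1-1 replicate 1 (0.057 and 0.14). GAPDH was also lost in DESeq2, in edgeR's likelihood ratio test and without the expression filter (adjusted p = 0.11, 0.12 and 0.14), and UBI4 without the filter (0.057). With TMM factors squared both were lost (0.40 and 0.11), and the log2 change of GAPDH was 0.05, against 0.07 without Bd21-3 replicate 1. Their adjusted p lay in ranges of 3.18e-04 to 0.40 and 1.70e-05 to 0.14 over the alternatives.

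**Figure D2:**
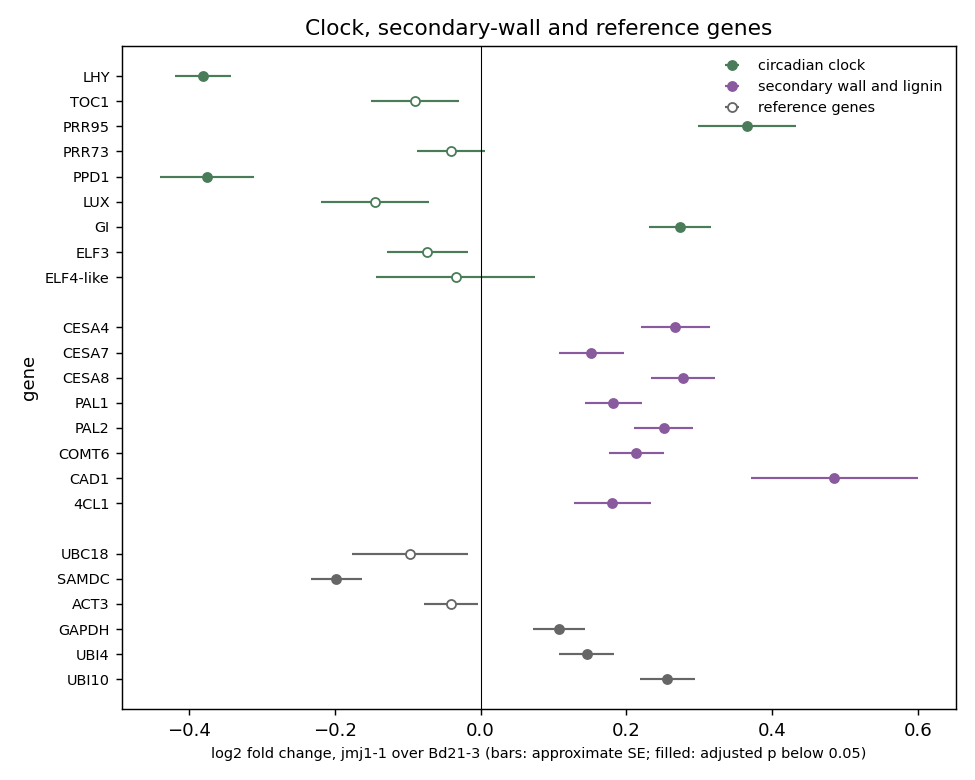
Log2 fold change of jmj1-1 over Bd21-3 for clock, secondary-wall and reference genes, with approximate standard errors as bars and filled points for adjusted p below 0.05. The 8 secondary-wall genes lie between 0.15 and 0.49, and the reference genes between -0.20 and 0.26.

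Over the whole transcriptome, 2978 of 21456 tested genes differed between the genotypes, 13.9% of them. In jmj1-1, 1315 were higher and 1663 were lower. Most changes were small, with a median of 1.26-fold, and 2207 of the calls (74.1%) were under 1.5-fold. Among the 434 called genes with a change of 2-fold or more the balance was the other way, with 313 higher and 121 lower. At 4-fold or more, 153 were higher and 36 lower. The split of all calls depended on the scaling. With library totals alone, 64.1% of calls were higher in jmj1-1 (2041 higher and 1143 lower), against 44.2% with TMM, while the median log2 change of all tested genes moved from 0.0033 to 0.057. With TMM factors squared, a scaling chosen after seeing the data that moves jmj1-1 the other way by about as much, 28.1% of calls were higher (953 higher and 2433 lower).

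The largest rises were at loci with almost no reads in the wild type. BRADI_1g57280v3 had 115 and 124 reads in the jmj1-1 libraries and 0 in both Bd21-3 libraries. It was 83.8-fold higher against the floor of 3 reads over the group. For the observed 239 reads against 0, whose ratio is undefined, the exact 95% interval had a lower end of 67.6 and no upper end. BRADI_3g21150v3 was at 31.3 ± 1.6 CPM in jmj1-1, with 951 reads over both libraries against 1 read in Bd21-3 (ratio 1000, 95% interval 179 to 39553). That single read was in Bd21-3 replicate 1, and the log2 change of 9.64 was 8.81 without Bd21-3 replicate 2. Without replicate 1 no read was left in Bd21-3, and the fitted value of 11.91 is no bound. The 12 largest falls that the naming rule picked began with VRN1, FT1 and FUL2. The fall ranked 10 had 237 and 9 reads in the Bd21-3 libraries and 22 and 18 in the jmj1-1 libraries, so it rested on Bd21-3 replicate 1.

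Among those 12 falls, the one with the most reads in Bd21-3 was at BRADI_2g60970v3, chosen after its values were seen like the locus named next. It went from 414.7 ± 16 to 13.8 ± 0.60 CPM, a log2 change of -4.91 (SE 0.062, adjusted p = 1.47e-56). BRADI_2g61050v3, which lies close to it by locus number, went from 44.8 ± 0.92 to 3.23 ± 0.14 CPM, a log2 change of -3.79 (SE 0.12, adjusted p = 1.83e-34). Of the 6 tested loci between them, 2 were called, and 1 of those was lower by 2-fold or more. What either locus encodes is not in the files used here.

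**Figure D3:**
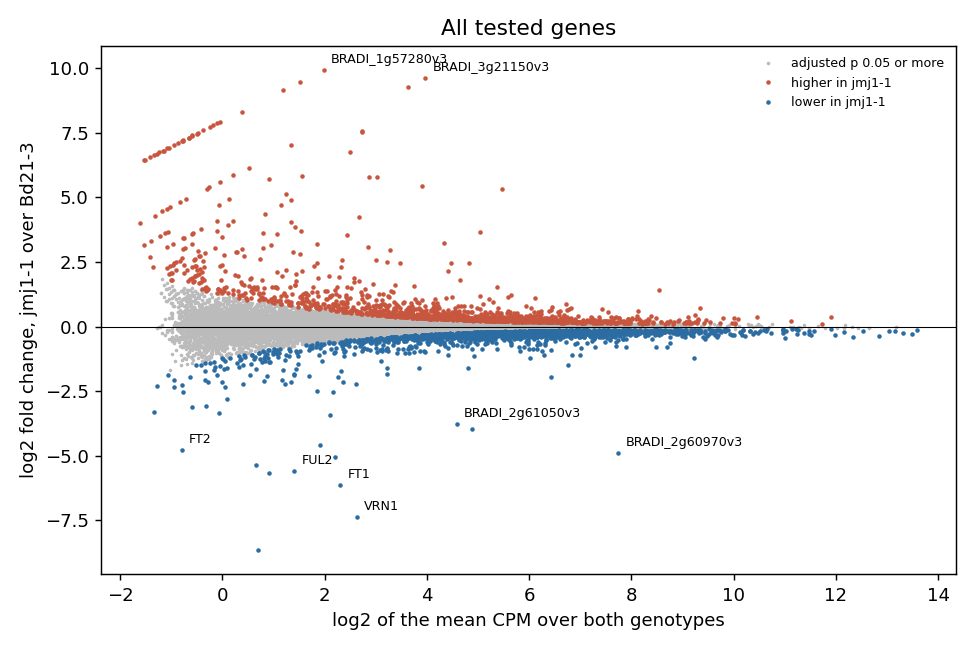
Log2 fold change of jmj1-1 over Bd21-3 against the log2 mean CPM of each of the 21456 tested genes, with genes at adjusted p below 0.05 coloured by direction. Most called genes lie near 0, while VRN1, FT1, FUL2 and FT2 lie at or below -4.79.

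The number of calls depended on the filter and on the tool. It fell whichever library was left out, and fewer libraries also leave less power. The number was 1788 without the expression filter. DESeq2 called 1283 genes, each of them also called by edgeR's quasi-likelihood test in the same direction. VRN1, FT1, FUL2, FT2, PPD1, GI, LHY and PRR95 passed an adjusted p of 0.05 with each library left out and under every scaling, filter and tool tried.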

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

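Without the expression filter, 1788 genes were called (746 higher, 1042 lower), with 76 lower by 2-fold or more. DESeq2 called 1283 (515 higher, 768 lower), with 187 higher and 54 lower by 2-fold or more. At an adjusted p of 0.01, 1954 genes were called and 837 were higher. Tested against a fold of 1.5, 276 genes were called, 196 higher and 80 lower, with 189 and 58 of them at 2-fold or more. Library totals alone gave 2041 higher genes, and ACT3 turned to 0.0126. The stricter threshold and the fold test lower the counts by construction, and for the other settings the cause was not tested. Leaving out 1 library gave 1792 to 2856 calls, 749 to 1236 of them higher and 1042 to 1620 lower. These fits have less power with fewer libraries, and the lone library of a genotype is assumed to vary like the other genotype. The lowest counts came without jmj1-1 replicate 1 or 2. The 2978 calls shared 2972 genes in direction with RLE scaling, 2885 with the upper quartile, 2859 with limma-voom, 2817 with the likelihood ratio test and 1765 without the filter. None of the shared calls changed direction. VRN1 ranged from -7.56 to -6.97 and FT2 from -7.12 to -4.03, both ends of FT2 without 1 jmj1-1 replicate. The replicate block gave 3140 calls and changed no call of a named gene or of the flowering and clock lists. The correlation of deviations of same-numbered libraries was -0.018 and nothing in the labels pairs them. The flowering list was called and the clock list was not under the scalings, the filters, limma-voom, the replicate block, each left-out library, the estimated correlation and fry, the settings in which these lists were tested. CESA7, PAL1, 4CL1, CAD1, PIN1a, GAPDH, UBI4, SPCH1, SPCH2, PHYC and the CONSTANS-like gene of chromosome 1 crossed the threshold under at least 1 setting. The older quasi-likelihood method and TMM factors squared, chosen after seeing the data, gave 2956 and 3386 calls. At 13825916 to 16520046 reads per library, genes such as FT2 rest on few reads.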

Other observations

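The tests of deletions, of short segments, of scaling, of a floor at low counts and of shared handling below were chosen after the results were seen, and the stomatal and auxin lists after the identifiers were. Stomatal lineage genes did not pass the test over all genes (0 of 6 in edgeR's quasi-likelihood test, with 2 at an unadjusted p under 0.05, and neither of those passed in DESeq2). SPCH1 and SPCH2, bHLH genes that start the stomatal lineage, had log2 changes of -0.92 (SE 0.34, adjusted p = 0.057) and -1.31 (SE 0.50, adjusted p = 0.067) at 18 to 41 and 3 to 21 reads per library. Adjusted over the list alone, both were lower. They passed over all genes in edgeR's likelihood ratio test (adjusted p = 0.038 each) and with TMM factors squared (0.038 and 0.0497), SPCH1 also without Bd21-3 replicate 1 (0.043), and over the alternatives SPCH1 ranged from 0.038 to 0.47 and SPCH2 from 0.038 to 0.52. The log2 change of SPCH2 was -2.40 without jmj1-1 replicate 1 and -0.77 without jmj1-1 replicate 2. The list as a whole did not rank apart (camera adjusted p = 0.33). Of 4 auxin transport genes, PIN1a, an auxin efflux carrier gene, rose by 0.49 (SE 0.12, adjusted p = 0.0013), and its call was lost in DESeq2 (0.079) and without jmj1-1 replicate 1 (0.094), in a range of 2.77e-04 to 0.094. Non-coding ENSRNA loci were mostly lower where called, with 16 lower and 1 higher of 80 tested. They took 0.455% and 0.515% of reads in Bd21-3 and 0.368% and 0.451% in jmj1-1.

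Some loci were silent in one genotype and read in the other. With at most 2 reads over both libraries of one genotype and at least 40 in the other, 30 called loci met this, and 26 of them were silent in Bd21-3. Sampling at low counts is argued against, since 0 loci had at most 1 read in one library and at least 20 in the other between replicates, against 33 to 38 between libraries of different genotypes. A single chromosome segment that differs between the lines is argued against too, since the densest window of 500 tested loci held 13.3% of them. Deletions in the jmj1-1 line are argued against as the main cause, since 13.3% were silent in jmj1-1, VRN1 among them, and whether any of these is deleted was not tested. Adjacent loci shared the pattern more often than loci shuffled within chromosomes (3 pairs against a mean of 0.0385, permutation p = 0.0001). That p is the smallest these shuffles can give, but only 6 of the 30 loci were in such pairs. Many short segments may differ between the lines. Runs of duplicated or co-regulated genes, or reads shared by overlapping neighbours, would give the same count, and the mutation itself stays open.

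Rises outnumbered falls among changes of 2-fold or more, at 72.1% of 434 genes. Scaling errors of the size tried are argued against, but larger ones stay open. The lowest share of rises under 4 other scalings was 66.4% (exact 95% interval 61.8 to 70.7), with TMM factors squared. That scaling was the only one of them that moved jmj1-1 down, to a median log2 change of -0.050 over all tested genes. Larger downward shifts were not tried. For a floor at low counts, the share was 66.7% (exact 95% interval 58.99 to 73.7) of 168 genes at 1 CPM or more in both genotypes. That interval lies above 50%, so a floor is argued against as the only cause among these 168 genes. The interval reaches below the bound of 60%, so the prediction with that bound was not decided. The share was 70.5% (59.8 to 79.7) of 88 genes with a mean of 5 CPM or more, which keeps genes near 0 in one genotype. The 75.6% among genes under 1 CPM in either genotype decides nothing, so for those genes the floor and the genotype itself stay open. All these intervals treat genes as independent, and neighbours that change together may make them too narrow. The bound of 60% was set after the results were seen, so the readings on scaling and on the floor are tentative. Rises and falls of 2-fold or more both had neighbours of their own kind. Rises had 35 pairs against 4.54 in shuffled loci (permutation p = 0.0001, adjusted over 7 sets 0.00014). Falls had 5 pairs against 0.657 (permutation p = 0.0005, adjusted 0.00058). These pairs held 58 of 312 rises and 10 of 119 falls on numbered chromosomes. Calls of any size did so too, with 156 pairs against 80.7 for rises and 169 against 126.6 for falls (permutation p = 0.0001 each).

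Changes of any size cannot be told apart from handling shared by the 2 libraries of a genotype, such as growth position or harvest. Among changes under 1.5-fold, reference genes were called as well, up to 0.256 on the log2 scale, close to the changes at GI, CESA4 and CESA8. What keeps this open is that no library of either genotype is known to have been handled with the other. The same limit applies to the flowering, clock and secondary-wall genes and to the loci silent in one genotype.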
